A study of Mus musculus with 7 samples.

How the data were processed

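Per the labels' protocols, dorsal forebrain of CD-1 mouse embryos was dissociated with papain and single cells were captured with Drop-seq (protocol 3.1). Per the submitters' processing notes, the authors used Drop-seq tools 3.1 on the mm10 genome, and clustered cells with Seurat 3.1.5. The deposited values were counts, whole numbers of UMIs per gene and cell, in 1 matrix of 21862 genes and 10261 cells, with a gene symbol list and, for each cell, its library and 1 of 19 cluster numbers without names. The aligner, the gene annotation and the counted strand were not given in the sources used here. Every deposited cell had at least 501 genes and at most 9.996% mitochondrial UMIs, a property tested on the values themselves. The 12 libraries were matched to 7 samples by their names. For 1 library of the larger E14.5 sample no label lists the exact name, so that it was assigned by inference. The label of E16.5 also lists a library that no cell carries. With this assignment, all 10261 columns had a sample. 1 barcode occurred in 2 libraries of 1 sample and was kept in both.

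Cells with over 2% haemoglobin UMIs, 13 in all, were set aside as erythroid, with the lowest of them at 2.907% and the next cell at 0.584%. Clusters were named from 15 marker lists written before the data were examined. A cluster took the class with the most markers at least 2-fold higher than in other cells, with at least 3 needed. It stayed unnamed if another class had more markers among the 10 genes with the highest fold, or if pseudocounts of 1 and 5 CPM gave different names. Genes in at least 10% of the cluster's cells were used. Cluster 10 had none of its own list in its top 10 and was named from 31 of 42 markers at 2-fold. Counts were summed per class and sample where at least 20 cells were present, so that samples and not cells were the unit of each test. The 3 projection neurons of E10.5 were not used. Doublets were called with Scrublet per library at an expected rate of 5% (95 cells, 0.926%) and were left out only in an alternative.

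Slopes on embryonic day were fitted to class sums with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, estimateDisp, glmQLFit and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over the tested genes and 0.05 as the threshold. A slope of 1 means a doubling per day. Levels in trend comparisons are CPM over the TMM-scaled library size, and levels between neighbouring stages and in other cells are CPM over the plain total. The difference of slopes between apical progenitors and projection neurons was the interaction of class and day with sample as a block. The rule for naming genes was set before the data were examined: per class the 8 steepest called falls and rises with a mean of at least 50 CPM (6 each for differences), up to 4 called members per direction of the lists that fit the class, and 13 genes given in every class. Mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and unnamed gene models were left out of the steepest genes. A count of 0 is given with the level that 3 counts would have over the plain total.

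The 19 gene lists were written before the data were examined: radial glia, neuroepithelial and early-stage, late progenitor and glial, intermediate progenitor, temporal transcription factors, deep-layer neuron, upper-layer neuron, pan-neuronal, synapse, axon guidance, Notch pathway, Wnt pathway, S phase, G2 and M phase, glycolysis, cholesterol synthesis, extracellular matrix and adhesion, immediate early and heat shock, and erythroid. They were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01 and at least 3 measured genes, adjusted over the 55 tests in 3 classes. Camera with an estimated correlation and fry were the alternatives. The 19 lists held 464 genes, of which 461 were in the deposited gene list.

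Shares of cells were given with exact Clopper-Pearson 95% intervals and correlated with day over 7 samples, with exact permutation p-values adjusted over 7 classes. Neighbouring stages were compared without a test, because each had 1 sample except E14.5. Genes with at least 50 CPM in either sample counted as different at 2-fold, with 3-fold, 100 CPM and thinning to 272600 UMIs as alternatives. For identity genes, cells were thinned to 1000 UMIs, 1783 cells with fewer were left out, 0.5 was added to each count of a 2 by 2 table, and the mean log2 odds ratio over samples was tested by exact sign flips.

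Alternatives fixed before the data were examined were DESeq2 1.42.0, size factors instead of TMM, stage rank instead of day, no low count filter, thinned sums, the E14.5 samples summed, the library suffixes taken apart, only cells with at least 1000 UMIs or with at most 5% mitochondrial UMIs, doublets left out, clustering anew at resolution 2 and each sample left out in turn. Alternatives chosen after seeing the data were clustering anew at resolution 1, leaving out cluster 12, cluster 6 or 1 library of E14.5, adding cluster 0 to the neurons, keeping the erythroid cells, using intermediate progenitors alone, and trends in cluster 0 and in interneurons. Clustering anew used scanpy 1.11.5 (counts scaled to 1 total per cell, log1p, 2000 variable genes without mitochondrial, haemoglobin and sex-linked genes, 30 components, 20 neighbours, Leiden at resolutions 1 and 2). It gave 17 and 27 clusters, and 77.3% and 97.2% of the deposited apical progenitors kept their class, 93.0% and 93.1% of intermediate progenitors, and 99.7% of projection neurons at both.

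The fits were tested on simulated data with known slopes. Slopes of 0.3 per day were recovered for 94% of genes in apical progenitors, 67.3% in intermediate progenitors, 75% in projection neurons and 83.7% in cells with Eomes, and differences of 0.3 for 24%, while slopes of 0.6 were recovered for 100% in each class and differences of 0.6 for 92%. A simulated rising list of 20 genes was recovered in all 3 classes, and of 20 unchanged lists 0, 0 and 2 had camera p under 0.05. The changed genes were picked among those with a mean of at least 20 CPM. Every gene in a simulation had the same dispersion and slopes were straight lines, and for differences no sample effect was added. Genes that are lower or vary more may be recovered less often. The simulated genes were drawn independently of each other. The simulation therefore does not show how often the list test calls unchanged lists whose genes move together.

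Gene symbols were matched to GENCODE vM21 (mm10), which held 20389 of the 21862 symbols and 132 of 135 named genes. Gucy1a3, Ppap2b and RP23-442I7.1 were absent under these symbols. The exons of Dlg2, Gria3, H19, Igf2bp1, Nav2, Nrp1, Otx2, Pcp4 and Zbtb20 overlap another gene on the same strand, so their counts may hold reads of that gene, and 41 named genes overlap one on the other strand. No gene trend was fitted for endothelial, microglial, mural or mesenchymal cells or for cluster 14 as classes. A planned comparison of cell cycle genes within cells with Eomes, and the values of some single genes, are not reported. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for counting and figures were drawn with matplotlib 3.10.9.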

Results

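Single-cell RNA profiles of the dorsal forebrain of CD-1 mouse embryos were collected with Drop-seq, in which each captured mRNA molecule carries the barcode of its cell and a unique molecular identifier (UMI). The 7 samples covered 6 stages between embryonic day (E) 10.5 and E18.5, with 1 sample per stage except E14.5, which had 2. The deposited matrix held 27776936 UMIs. E10.5 gave 1172 cells with 4927189 UMIs and a median of 3299 UMIs per cell, and E12.5 gave 2668 cells with 5742982 UMIs and a median of 1708. The 2 samples of E14.5 gave 3235 cells with 6638760 UMIs (median 1645) and 507 cells with 1937378 UMIs (median 3352). E15.5 gave 1014 cells with 3482352 UMIs (median 2361), E16.5 gave 387 cells with 1519473 UMIs (median 3074), and E18.5 gave 1278 cells with 3528802 UMIs (median 2019.5). The median mitochondrial share of a cell's UMIs was 5.41% at E10.5, 3.83% at E12.5, 2.25% and 2.80% in the 2 samples of E14.5, 6.80% at E15.5, 7.22% at E16.5 and 7.53% at E18.5. The labels name no separate litters or cultures, so every p-value measures only the spread between these samples, which may be technical.

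The deposited cell labels gave 19 cluster numbers without names, and the clusters were named here from marker lists. Clusters 1, 3, 6, 10 and 12 were named apical progenitors, the dividing radial cells that line the ventricle. Clusters 4 and 7 were named intermediate progenitors, the Eomes-expressing daughter cells that divide away from the ventricle. Clusters 2, 5, 9 and 11 were named projection neurons, cluster 8 interneurons and cluster 13 Cajal-Retzius cells, the early reelin-secreting neurons of the cortical surface. Cluster 0, with 1812 cells led by Unc5d, Pcp4, Slc17a6, Nhlh1 and Neurod1, had 3 intermediate progenitor markers among its top 10 genes but 14 projection neuron markers at 2-fold, and stayed unnamed, as did cluster 14. The clusters that held a class changed with stage. Cluster 6, led by Hmga2, Dlk1, Otx2 and Crabp2, held 90.8% of the apical progenitors at E10.5, and cluster 12, led by Olig1, Olig2, Tnc and Egfr, held 83.4% at E18.5. Clusters 1 and 3 held 41.3% and 41.9% of them at E12.5. Cluster 7 held 75.8% of the intermediate progenitors at E10.5 and cluster 4 held 65.2% at E18.5. Cluster 2, led by Cdh13, Sox5 and Bcl11b, held 91.8% of the projection neurons at E12.5, and cluster 5, led by Gucy1a3, Nefl and Mef2c, held 65.7% at E18.5. The apical progenitor sums ranged from 272600 UMIs over 60 cells at E16.5 to 2848705 UMIs over 684 cells at E10.5, the intermediate progenitor sums from 105152 to 1139796 UMIs, and the projection neuron sums from 736657 to 1992455 UMIs.

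The first question was how the make-up of the tissue changed over the stages. Apical progenitors fell from 58.7% of cells at E10.5 (95% exact Clopper-Pearson interval 55.8 to 61.6, counting error only) to 45.1% at E12.5, 31.4% and 19.1% at E14.5, and 15.1% at E18.5 (13.2 to 17.2). Projection neurons rose from 0.257% at E10.5 (0.0531 to 0.751), 3 cells in all, to 12.8% at E12.5, 42.2% at E15.5 and 53.7% at E18.5 (50.9 to 56.5). Intermediate progenitors made up 2.83% at E10.5, 20.5% at E12.5, 11.4% at E15.5 and 3.61% at E18.5. Interneurons made up between 1.87% at E12.5 and 11.9% at E16.5, and Cajal-Retzius cells between 0.862% at E12.5 and 5.67% at E10.5. Over the 7 samples, the apical progenitor share fell with embryonic day (Pearson r = −0.907, two-sided exact permutation p = 0.00317, adjusted p = 0.0111 over 7 classes; Spearman rho = −0.883, p = 0.0135, adjusted p = 0.0315). Its r was −0.903 without E10.5 and E18.5, the samples farthest from the median day. The projection neuron share rose (r = 0.983 and rho = 0.991, exact permutation p = 0.000794 for both, adjusted p = 0.00556), with r = 0.969 without those 2 samples. The interneuron share had r = 0.801 (exact permutation p = 0.0317, adjusted p = 0.0741) and rho = 0.919 (exact permutation p = 0.00635, adjusted p = 0.0222), so only the rank correlation passed. It no longer did without E12.5 (adjusted p = 0.0583), without either E14.5 sample (0.117), without E15.5 (0.0778) or in cells with at least 1000 UMIs (0.115). Its r was 0.891 without the 2 samples. The intermediate progenitor share (r = −0.212, exact permutation p = 0.656; rho = −0.234, p = 0.62) and cluster 0 (r = 0.351, p = 0.443; rho = −0.018, p = 0.986) did not pass. Neither did Cajal-Retzius cells (r = −0.407, p = 0.386; rho = 0.018, p = 0.986) and cluster 14 (r = −0.673, p = 0.247; rho = −0.0818, p = 0.863). The adjusted p of these 4 lay between 0.432 and 0.986. Their r without the same 2 samples was −0.999, −0.126, 0.615 and 0.789. Leaving out E12.5 ended the call for apical progenitors (r = −0.892, adjusted p = 0.0778), and leaving out either E14.5 sample ended that of their rank correlation (adjusted p = 0.136). Leaving out E10.5 ended the call as well (r = −0.807, adjusted p = 0.0519) and gave intermediate progenitors a call (r = −0.997, adjusted p = 0.0194), whose sign turned without E18.5 (r = 0.167).

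**Figure D1:**
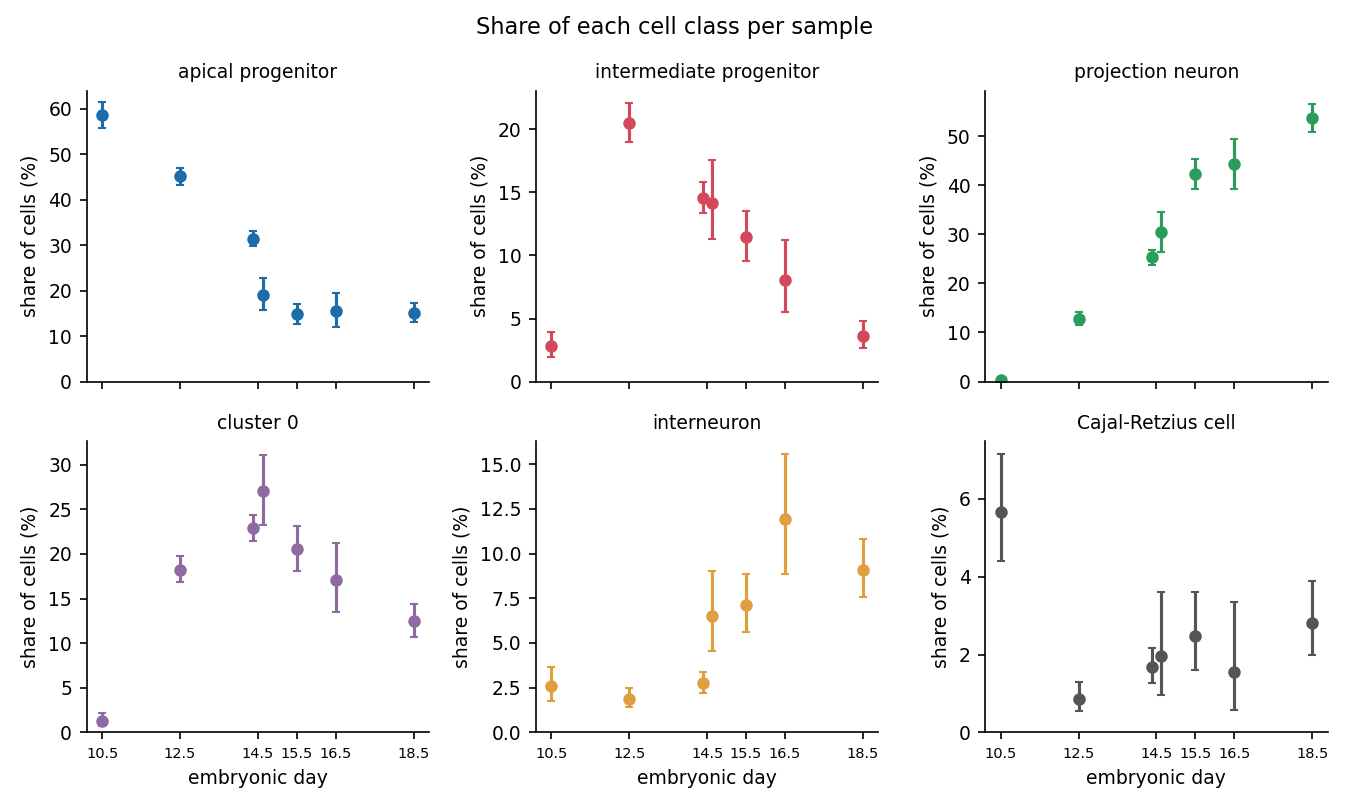
Share of cells in percent (vertical axis) against embryonic day (horizontal axis) for 6 cell groups, with 1 point per sample, exact 95% intervals as bars and the 2 samples of E14.5 drawn slightly apart. Apical progenitors go from 58.7% at E10.5 to 15.1% at E18.5, projection neurons from 0.257% to 53.7%, and intermediate progenitors are highest at E12.5 with 20.5%.

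Next, the genes of apical progenitors were followed over embryonic day, to ask how progenitors change as neurogenesis proceeds. The steepest falls were of Crabp2, which binds retinoic acid (chromosome 3, 87948666 to 87953376, mm10, ENSMUSG00000004885), and Hmga2, a chromatin protein of early stem cells (chromosome 10, 120361275 to 120476469, ENSMUSG00000056758). Crabp2 fell by 1.32 log2 units per day (SE 0.0628, n = 7 samples, edgeR adjusted p = 2.63e-07), from 447 CPM, counts scaled to the class total, at E10.5 to no count at E16.5 and E18.5, where 3 counts would give 11.01 and 4.95 CPM. Hmga2 fell by 1.28 per day (SE 0.0740, adjusted p = 1.46e-06), from 1080 to 3.53 CPM. Smaller falls were found for the RNA-binding proteins Igf2bp2 (−0.47, 207.5 to 10.6 CPM) and Igf2bp1 (−0.41), for Hook1, a microtubule linker (−0.38), for the adhesion genes Cntnap2 (−0.39) and Pcdh19 (−0.38), and for Lix1 (−0.40). The steepest rises were of Olig1, a transcription factor of the oligodendrocyte lineage (chromosome 16, 91269772 to 91271933, ENSMUSG00000046160; 1.89 per day, SE 0.140, adjusted p = 6.88e-06, 0.748 to 744 CPM), and Slco1c1, a thyroid hormone transporter (1.43). Next came Tnc, an extracellular matrix glycoprotein (chromosome 4, 63959785 to 64047015, ENSMUSG00000028364; 1.35, SE 0.161, adjusted p = 0.000361, 0 to 1122 CPM, where 3 counts at E10.5 would give 1.05 CPM). The secreted matrix protein gene Sparcl1 rose by 1.29, Ccdc80 by 0.97, the proteoglycan gene Bcan by 0.93 and Tmem132b by 0.91. Of the genes chosen beforehand, Pou3f2, a transcription factor of upper-layer fate, rose by 0.27 (adjusted p = 0.0339), while Ccnd1 (−0.19, adjusted p = 0.171; −0.42 and adjusted p = 0.00707 without E18.5, 0.02 without E10.5), Pax6 (−0.07), Sox2 (−0.01), Hes5 (−0.02), Neurog2 (0.05), Eomes (0.25), Bcl11b (−0.10) and Fezf2 (−0.05) did not pass. In all, 536 genes rose and 245 fell among 8392 tested (edgeR quasi-likelihood test of the slope, Benjamini-Hochberg adjusted p under 0.05), 781 in total against 401 without E10.5 and 408 without cluster 12, a setting chosen after seeing the data. There were 273 with at most 5% mitochondrial UMIs (6 samples), 238 with library suffix 1 (5 samples), 415 with thinned sums and 1384 with no low count filter. Olig1 and Egfr were too low to be tested without cluster 12, which they lead, and Sparcl1 then rose by 0.77. Without cluster 6, Hmga2 fell by 1.21 and Crabp2 by 1.06. Without E10.5, calls were lost for Cntnap2 (−0.30), Hmga1 (−0.31), Igf2bp1 (−0.22), Pou3f2 (0.21), Ptn (0.20), Tcf4 (0.12) and Tmem132b (0.71). The call of Pou3f2 also ended without E12.5 (0.27), the smaller E14.5 sample (0.27) or E16.5 (0.26), that of Ptn without the smaller E14.5 sample (0.37), E15.5 (0.37), E16.5 (0.36) or E18.5 (0.44), and that of Tcf4 without E12.5 (0.35), the smaller E14.5 sample (0.33), E15.5 (0.31) or E16.5 (0.35).

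**Figure D2:**
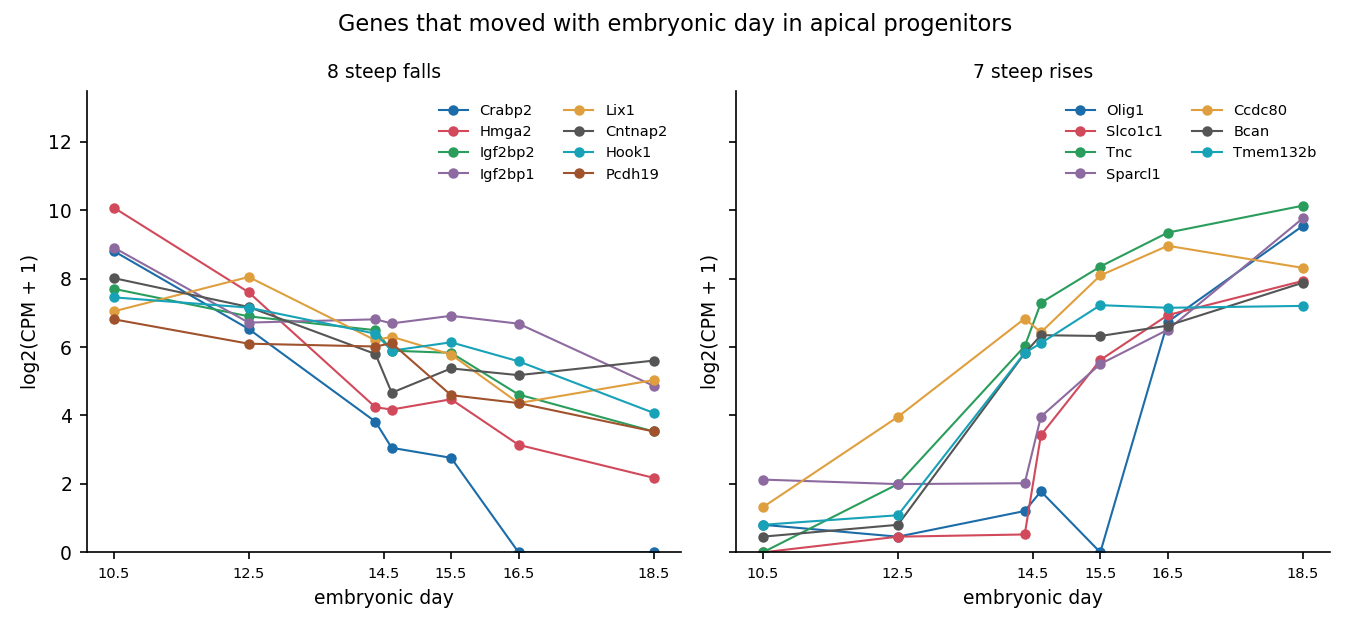
Level in apical progenitors as log2(CPM + 1) (vertical axis) against embryonic day (horizontal axis) for 8 genes with a steep fall and 7 with a steep rise, 1 point per sample, with the 2 samples of E14.5 drawn slightly apart. Hmga2 goes from 1080 CPM at E10.5 to 3.53 CPM at E18.5, and Olig1 from 0.748 to 744 CPM.

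Gene groups fixed beforehand were then compared with all other genes in apical progenitors. Of 30 late progenitor and glial genes, 26 rose, 0 fell and 4 did not pass (29 rose when adjusted over the list alone), among them Cd9 (0.69), Hopx (0.62, 23.9 to 697 CPM) and Egfr, the epidermal growth factor receptor (1.91). The list rose with camera adjusted p = 1.96e-22, and adjusted p = 0.0409 with an estimated correlation. Of 39 S phase genes, 22 fell and none rose (36 fell when adjusted over the list alone, camera adjusted p = 1.27e-15, and adjusted p = 0.0449 with an estimated correlation), with a median slope of −0.15. These were the only 2 of the 26 lists called in the 3 classes whose call held with an estimated correlation. The S phase genes Ung and E2f8 were among those that lead clusters 1 and 3. These clusters held 4.97% and 4.09% of the class at E10.5, 41.3% and 41.9% at E12.5, and 2.59% and 1.04% at E18.5. Whether the fall of S phase genes came from this change of clusters was not tested. Of 17 neuroepithelial and early-stage genes, 8 fell and 2 rose (10 and 2 adjusted over the list alone, camera adjusted p = 9.46e-05, adjusted p = 0.0868 with an estimated correlation). The 2 that rose were Ptn, a secreted growth factor also made by glia (0.38), and H19, an imprinted noncoding RNA (0.18), whose call ended without E12.5, the larger E14.5 sample, E15.5, E16.5 or E18.5 (0.17, 0.18, 0.17, 0.17 and 0.12). Of 18 radial glia genes, 6 rose, 1 fell and 11 did not pass (7 and 3 adjusted over the list alone). The glutamate transporter gene Slc1a3 rose by 0.72, the lipid-binding protein gene Fabp7 by 0.62 (430 to 13270 CPM), Mfge8 by 0.77 and the endothelin receptor gene Ednrb by 0.34, while Lix1 fell. That list had camera adjusted p = 0.0404, adjusted p = 0.604 with an estimated correlation, and 0.997 without E10.5, 0.0793 without the smaller E14.5 sample, 0.0714 without E15.5 and 0.0889 without E16.5. Neuronal transcripts also rose in this class: 9 of 21 pan-neuronal genes, with the microtubule genes Mapt, Map2, Dcx and Stmn2 among them (11 rose and 1 fell adjusted over the list alone, camera adjusted p = 6.1e-05, adjusted p = 0.269 with an estimated correlation, 0.146 without E18.5). So did 5 of 10 synapse genes (6 adjusted over the list alone, camera adjusted p = 0.000106, adjusted p = 0.0868 with an estimated correlation, 0.0889 without E18.5). The immediate early genes Egr1, Fos, Fosb and Jun rose, 4 of 13 members of the stress list (4 adjusted over the list alone, camera adjusted p = 0.0328, adjusted p = 0.376 with an estimated correlation, 0.13 without E18.5, 0.0604 without E12.5 and 0.053 without E16.5). Beside this, the median mitochondrial share lay between 2.25% and 7.53% over the samples.

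The other lists did not pass in apical progenitors. Of 17 temporal transcription factors, 4 rose, Zbtb20 (0.61), Nfia (0.50), Tcf4 (0.34) and Pou3f2 (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.116). Of 52 G2 and M phase genes, 2 rose and 1 fell (adjusted p = 0.754). None of 15 Notch pathway genes (0.971; median −0.02, mean 0.00, test up) and none of 21 cholesterol synthesis genes (0.252) passed. For the Wnt pathway 2 of 18 rose, Dkk3 and Fzd9 (0.867; median −0.03, mean 0.02, test down). For axon guidance 5 of 23 rose and 1 fell (0.0607), and for extracellular matrix and adhesion 7 of 21 rose and 1 fell (0.0607). For glycolysis 1 of 16 fell, Pkm (0.224), and for intermediate progenitor genes 1 of 13 fell, Rcor2 (0.481). For deep-layer genes 2 of 14 rose, Etv1 and Zfpm2 (0.484; median −0.04, mean 0.08), and for upper-layer genes 4 of 12 rose and 1 fell (0.09). Of 2 measured erythroid genes Hbb-y fell, and the list was too short for a set test.

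Neighbouring stages were set side by side without a test, since each had 1 sample, with the pair of E14.5 samples as a yardstick. Between E10.5 and E12.5, 246 of 4407 genes with at least 50 CPM in either sample differed at least 2-fold in apical progenitors, 177 higher and 69 lower at E12.5, which is 5.58%, against 225 of 4797 genes, 4.69%, between the E14.5 samples. From E12.5 to E14.5 it was 3.14% with the larger and 10.3% with the smaller E14.5 sample, and from these to E15.5 it was 4.49% and 9.70%. From E15.5 to E16.5 it was 7.97%, and from E16.5, the smallest sum, to E18.5 it was 13.1%. The glial aldolase gene Aldoc was 54.4-fold higher at E12.5 (267 against 4.92 CPM, Poisson interval of the ratio 32.2 to 99.9, counting error only). With 3 counts set in place of 0, the retinaldehyde-binding protein gene Rlbp1 was 87.9-fold higher (92.6 CPM against no count in 2848705 UMIs, lower limit of the interval 71.0). Neurod6, a neuronal transcription factor, was 59.3-fold higher on the same floor (lower limit 47.7). Projection neurons rose from 0.257% to 12.8% of cells between these samples. Whether the Neurod6 counts came from free RNA or doublets was not tested. Ndrg2 was 77.2-fold higher on 3 counts at E10.5 (26.1 to 377), Rgs20 36.7-fold, the ephrin receptor gene Epha5 34.4-fold, RP23-442I7.1 17.6-fold and Ppp2r2b 15.9-fold. Higher at E10.5 were Dlk1, an imprinted Notch-like ligand (46.4-fold, 185 against 3.99 CPM; chromosome 12, 109452823 to 109463336), Igdcc3 (20.3-fold), the RNA-binding protein gene Lin28b (20.1-fold), the cell cycle inhibitor gene Cdkn1c (17.98-fold), the transcription factor genes Otx2 (16.9-fold) and Zic1 (9.52-fold), Fndc3c1 (8.33-fold) and the immediate early gene Fos (6.61-fold). Dlk1, Lin28b, Otx2 and Fndc3c1 also led cluster 6, which held 90.8% of the class at E10.5 and 3.41% at E12.5. With the sums thinned to 272600 UMIs, 662 genes (14.4%) differed between E10.5 and E12.5 and 601 (12%) between the E14.5 samples. Below that 12% lay E12.5 to the larger E14.5 sample (10.85%), that sample to E15.5 (11.8%) and E15.5 to E16.5 (11.5%). Above it lay E12.5 to the smaller E14.5 sample (16.95%), that sample to E15.5 (14.7%) and E16.5 to E18.5 (17.25%). At 3-fold, without thinning, 100 genes differed between E10.5 and E12.5 and 26 between the E14.5 samples.

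The same question was put to intermediate progenitors. The steepest fall was of Crabp2, at −1.40 per day (SE 0.109, n = 7, edgeR adjusted p = 2.0e-05, 574 to 0 CPM, where 3 counts at E18.5 would give 26.5 CPM). The proneural transcription factor genes Nhlh2 (−0.88, 856 to 0 CPM) and Neurog1 (−0.64, SE 0.0838, adjusted p = 0.00194, 388 to 0 CPM) followed. Cyclin D1 (Ccnd1) fell by 0.55 (697 to 50.3 CPM), the cell cycle inhibitor gene Cdkn1c by 0.55 (2665 to 60.4 CPM), Igf2bp1 by 0.55, Id4 by 0.55, the Notch ligand gene Dll1 by 0.51, Rgs16 by 0.62 and Nhlh1 by 0.36. The immediate early transcription factor gene Egr1 rose by 1.23 (SE 0.190, adjusted p = 0.00406, 0 to 714 CPM, where 3 counts at E10.5 would give 23.8 CPM), beside median mitochondrial shares of 5.41% at E10.5 and 7.53% at E18.5. Zbtb20, a late temporal transcription factor (chromosome 16, 42875881 to 43642602, ENSMUSG00000022708), rose by 0.67 (SE 0.0649, adjusted p = 0.000155, 52.9 to 2263 CPM). Rises were also found for Igfbp5 (0.75), Gamt (0.70), Acot1 (0.70), Pcp4 (0.64), the semaphorin gene Sema3c (0.64), Cdk6 (0.64) and the netrin receptor gene Unc5d (0.61). Eomes (0.05), Pax6 (0.11), Sox2 (0.08), Neurog2 (0.04), Hes5 (−0.31), Pou3f2 (0.26), Tbr1 (−0.24), Bcl11b (−0.25) and Fezf2 (−0.09) did not pass. In all, 39 genes rose and 39 fell among 5505 tested, 78 in total against 141 with DESeq2, 161 without E18.5, 31 without E10.5, 32 without E12.5, 43 without E15.5, and 47 without E16.5 or the larger E14.5 sample. Of 50 orders of the days, the real one included, 3 gave at least as many genes, up to 88, so the number of calls in this class was not beyond chance. Of 19 named genes with a call, 6 kept it in every fit with 1 sample left out that tested them, which for Crabp2 were 3 of 7. Without E10.5 the calls of Nhlh2 (−0.48), Rgs16 (−0.19), Cdkn1c (−0.34), Ccnd1 (−0.37), Dll1 (−0.39), Igf2bp1 (−0.41), Nhlh1 (−0.35), Cdk6 (0.60) and Unc5d (0.56) ended. Calls also ended without E12.5 for Cdk6 (0.52), Unc5d (0.48), Gamt (0.64) and Id4 (−0.46), and without E16.5 for Cdk6 (0.65), Unc5d (0.59) and Id4 (−0.55). Without the larger or the smaller E14.5 sample that of Cdk6 ended (0.63 and 0.63), and without E15.5 that of Unc5d (0.59). Without E18.5 those of Igfbp5 (0.33), Sema3c (0.45), Gamt (0.78) and Id4 (−0.52) ended. Igfbp5 turned to −0.22 clustered anew at resolution 2 and to −0.26 at resolution 1. Among cells with at most 5% mitochondrial UMIs, which left 4 of 7 samples, all 15 calls that could be tested ended, with Zbtb20 at 0.78, Ccnd1 at −0.74 and Rgs16 at −0.07. The smaller number of samples and the mitochondrial share were not told apart.

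Among the lists in intermediate progenitors, 3 of 17 intermediate progenitor genes fell, Neurog1, Dll1 and Nhlh1 (7 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00573, adjusted p = 0.178 with an estimated correlation, 0.0598 without E18.5). Of 13 neuroepithelial genes 5 fell (7 adjusted over the list alone, camera adjusted p = 0.000955, adjusted p = 0.178 with an estimated correlation). Of 50 G2 and M phase genes 2 fell, Aurka and Cdc25c (6 adjusted over the list alone, camera adjusted p = 7.96e-06, adjusted p = 0.604 with an estimated correlation, 0.383 without E10.5). Of 9 Notch pathway genes Dll1 fell (3 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.303 with an estimated correlation, 0.0548 without E18.5). Late progenitor genes were called upwards (2 of 14 rose, Mt3 and Cst3; 6 and 1 adjusted over the list alone, camera adjusted p = 0.00143, adjusted p = 0.239 with an estimated correlation). So were temporal transcription factors (2 of 18, Zbtb20 and Tcf4; 8 and 1 adjusted over the list alone, camera adjusted p = 0.00123, adjusted p = 0.429 with an estimated correlation, 0.0707 without E10.5). Upper-layer genes were called upwards as well (1 of 13, Unc5d; 6 adjusted over the list alone, camera adjusted p = 0.00352, adjusted p = 0.318 with an estimated correlation, 0.112 without E10.5). Synapse genes were called up with no member past the test over all genes (0 of 6; 3 adjusted over the list alone, camera adjusted p = 0.000106, adjusted p = 0.223 with an estimated correlation, 0.0827 without E18.5 and 0.053 without E16.5). Pan-neuronal genes were called up too, and of them Mapt rose and Tubb3 fell among 22 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.303 with an estimated correlation, 0.368 without E10.5, 0.0863 without the larger E14.5 sample, 0.121 without E15.5, 0.0929 without E16.5 and 0.0757 without E18.5). The lists of S phase (0 of 36 passed, camera adjusted p = 0.0654), Wnt pathway (0 of 7, 0.605), axon guidance (2 of 18 rose, 0.09) and cholesterol synthesis (0 of 12, 0.0522) did not pass. The lists of deep-layer (1 of 6 rose, Pcp4, 0.849; median −0.06, mean 0.02), extracellular matrix (0 of 12, 0.302), glycolysis (0 of 11, 0.882; median −0.01, mean 0.04), immediate early (1 of 10 rose, Egr1, 0.136) and radial glia genes (2 of 15 rose, 1 fell, 0.827; median −0.07, mean −0.02, test up) did not pass either, and 0 erythroid genes were measured.

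Cells with at least 1 Eomes UMI, whatever their cluster, were followed to ask which layer identity genes accompany Eomes (chromosome 9, 118478212 to 118486132, ENSMUSG00000032446), the transcription factor of intermediate progenitors, at each stage. There were 1803 such cells. Eomes itself was seen in 0.803% of endothelial, microglial, mural and mesenchymal cells, which should lack it, and in none of 211 of them thinned to 1000 UMIs. The mesenchymal cells among them came only from E10.5. At E10.5, 49.3% of 69 were Cajal-Retzius cells and 26.1% intermediate progenitors; at E12.5, 67.8% of 640 were intermediate progenitors, and at E18.5, 41.1% of 95 belonged to cluster 0 and 37.9% were intermediate progenitors. Of 21 upper-layer genes 6 rose in them and none fell (12 adjusted over the list alone). Unc5d rose by 0.60, Pou3f2 by 0.32 (SE 0.0582, n = 7, edgeR adjusted p = 0.00792, 126.5 to 572 CPM), Mef2c by 0.49 and Bhlhe22 by 0.29. Of 13 deep-layer genes, Tbr1, a regulator of layer 6 neurons, fell by 0.22 (adjusted p = 0.0318), Zfpm2 rose by 0.57 and Pcp4 by 0.53, while Bcl11b (−0.22) and Fezf2 (−0.11) did not pass. Of 17 intermediate progenitor genes 6 fell and none rose (7 and 1 adjusted over the list alone), among them Dll1 (−0.44), Dll3 (−0.49), Neurog1 (−0.63) and Mfng (−0.22). Of 51 G2 and M phase genes 10 fell and none rose (32 fell adjusted over the list alone), and of 16 neuroepithelial genes 8 fell and 1 rose. No set test was run on these lists. The steepest falls were of Crabp2 (−1.57, SE 0.0796, adjusted p = 3.65e-08), the cell cycle genes Cdkn1a (−0.72) and Ccnd1 (−0.57), Igf2bp1 (−0.55), Gadd45a (−0.52), Rgs16 (−0.51) and St18 (−0.49), and Hmga2 fell by 1.35. Cdkn1a is also in the marker list of Cajal-Retzius cells, which made up 49.3% of the cells with Eomes at E10.5 and 2.1% at E18.5. Trends in cells with Eomes were not told apart from this change of cell types. The steepest rises were of Nfix (0.74), Zbtb20 (0.72, SE 0.0602, adjusted p = 1.84e-05, 48.4 to 2415 CPM), Sema3c (0.64), Acot1 (0.59), Chl1 (0.57) and Fos (0.55). Cux2 (−0.06), Hes5 (−0.30), Pax6 (0.10), Sox2 (0.08) and Neurog2 (0.06) did not pass. In all, 121 genes rose and 95 fell among 7782 tested, 216 in total against 122 without E10.5, 102 without E12.5, 120 without E15.5 and, without E16.5, 72 rising and 56 falling. Of 26 named genes with a call, 11 kept it in every fit with 1 sample left out that tested them, which for Crabp2 and Hmga2 were 5 of 7. Without E10.5 that of Tbr1 (−0.13), Rgs16 (−0.16), Nfix (0.45), Gadd45a (−0.34), Pcp4 (0.35), Mef2c (0.52), Zfpm2 (0.53), Dll3 (−0.43) and Bhlhe22 (0.22) ended. Without E18.5 calls ended for Sema3c (0.40), Fos (0.48), Cdkn1a (−0.76), Chl1 (0.65), Mfng (−0.20), Bhlhe22 (0.31), Mef2c (0.61) and Zfpm2 (0.58). Calls also ended without E12.5 for Tbr1 (−0.22), Mef2c (0.35), Mfng (−0.19), Nfix (0.60) and Pcp4 (0.51), and without the larger E14.5 sample for Fos (0.52). They ended without E15.5 for Tbr1 (−0.20), Mef2c (0.50), Cdkn1a (−0.72), Fos (0.54) and Nfix (0.74), and without E16.5 for Tbr1 (−0.21), Cdkn1a (−0.70), Fos (0.54) and Nfix (0.79). Among cells with at most 5% mitochondrial UMIs, which left 4 of 7 samples, Cdkn1a turned to 1.20 (adjusted p = 0.117).

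Within apical progenitors, intermediate progenitors and projection neurons, each cell was thinned to 1000 UMIs, and 16 identity genes were compared between cells with and without Eomes. None passed in the exact sign-flip permutation test over 7 samples (two-sided, smallest possible p = 0.0156, smallest adjusted p = 0.15 over 16 genes; 5 genes had an unadjusted p under 0.05). In cells not thinned, Tle4, Foxp2, Pou3f2, Pou3f3 and Mef2c had the same sign in 7 of 7 samples and an adjusted p of 0.05, at the threshold and not under it. With this smallest possible p, 5 such genes among 16 could not pass. That none passed therefore says little about an association with Eomes. The mean log2 odds ratio was 1.70 for Foxp2 (SD 0.740, above 0 in 7 of 7 samples), 1.01 for Pou3f2 (6 of 7) and 0.92 for Pou3f3 (6 of 7). It was −1.56 for Tle4, −2.41 for Mef2c and −1.46 for Bcl11b (each below 0 in 6 of 7), with 0.46 for Tbr1 and 0.11 for Fezf2. The comparison pools 3 classes. Within intermediate progenitors alone, a setting chosen after seeing the data, the values were 0.36 for Foxp2 (above 0 in 3 of 7 samples), 0.12 for Pou3f2 (2 of 7), 0.04 for Pou3f3 (2 of 7), −0.64 for Tle4 and −0.44 for Mef2c. After thinning, Pou3f2 was seen in 18.2% of 807 cells with Eomes (median 2062 UMIs; 31.5% without thinning), against 12.4% of projection neurons (median 2650 UMIs) and 0.474% of 211 endothelial, microglial, mural and mesenchymal cells (median 4159 UMIs; 1.20% without thinning), which should lack it. Fezf2 was seen in 17.97%, 28.9% and 0%, Bcl11b in 9.17%, 40.4% and 4.74%, and Tbr1 in 8.30%, 17.03% and 0%. Foxp2, at 4.09%, lay below the 8.06% in the vascular, microglial and mesenchymal cells. Whether that share is background or their own expression was not tested. All 142 mesenchymal cells, counted before thinning, came from E10.5, where projection neurons made up 0.257% of cells. The shares in these cells are therefore a weak guide to free RNA of neurons at later stages. Thinning left out 581 apical progenitors, 266 intermediate progenitors and 332 projection neurons with fewer than 1000 UMIs. Tbr1 turned to −0.57 without E10.5 and Fezf2 to −0.10.

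Projection neurons were followed over 6 samples from E12.5 on, to ask how neurons of successive stages differ. Tbr1 (chromosome 2, 61802930 to 61814114, ENSMUSG00000035033) fell by 0.52 per day (SE 0.0522, n = 6, edgeR adjusted p = 0.000343, 434 to 57.4 CPM). Sox5, a regulator of deep-layer differentiation (chromosome 6, 143828425 to 144781977, ENSMUSG00000041540), fell by 0.77 (SE 0.154, adjusted p = 0.0173, 744 to 44.8 CPM). Bcl11b, a regulator of subcerebral neurons, fell by 0.48 (905 to 130 CPM), Fezf2 by 0.49 (adjusted p = 0.0484) and Wnt7b by 0.49. Pou3f2 (chromosome 4, 22482780 to 22488366, ENSMUSG00000095139) rose by 0.82 (SE 0.179, adjusted p = 0.0273, 5.82 to 322 CPM), and Ptn by 0.76, Ptprk by 0.64, Pou3f3 by 0.55, Cux2 by 0.47 and Mef2c by 0.45 (SE 0.0616, adjusted p = 0.00216, 236 to 1176 CPM). The other steep falls were of the receptor tyrosine kinase gene Kit (−0.72), the GTPase gene Rnd3 (−0.72), St18 (−0.68), Kif26a (−0.63), Cntnap2 (−0.59) and Cdh13 (−0.52). The other steep rises were of Zbtb20 (0.97, SE 0.149, adjusted p = 0.0043, 22.1 to 2007 CPM), March1 (0.75), Lsamp (0.74), the semaphorin receptor gene Nrp1 (0.68), the neuropeptide gene Cck (0.64) and Gucy1a3 (0.60). Cdh13, Sox5, Bcl11b and Kit led cluster 2, which held 91.8% of the class at E12.5, and Gucy1a3 and Mef2c led cluster 5, which held 65.7% at E18.5. Hes5 (−0.71), Eomes (−0.22), Pax6 (−0.07), Sox2 (−0.02) and Neurog2 (−0.10) did not pass. In all, 199 genes rose and 100 fell among 9712 tested, 299 in total against 187 without the larger E14.5 sample, 147 without E16.5 and 166 without E18.5. There were 110 with at most 5% mitochondrial UMIs, 49 with library suffix 1, 684 with no low count filter, 465 clustered anew at resolution 2 and 652 with cluster 0 added, a setting chosen after seeing the data. Without E18.5, calls ended for Sox5 (−0.38), Bcl11b (−0.21), Fezf2 (−0.24), Wnt7b (−0.44), Cdh13 (−0.32), Kif26a (−0.25), St18 (−0.54), Cux2 (0.49) and Cck (0.45), without E12.5 those of Pou3f2 (0.60) and Gucy1a3 (0.52), and without E16.5 those of Nrp1 (0.65), Pou3f2 (0.73), Sox5 (−0.77), Bcl11b (−0.49), Fezf2 (−0.46) and Kif26a (−0.65). The call of Fezf2 also ended without the smaller E14.5 sample (−0.49) or E15.5 (−0.49), and that of Kif26a without the smaller E14.5 sample (−0.61).

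In projection neurons 12 of 22 upper-layer genes rose and none fell (15 and 1 adjusted over the list alone, camera adjusted p = 3.36e-09, adjusted p = 0.178 with an estimated correlation). Of 20 deep-layer genes, 5 fell and none rose (6 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.0288, adjusted p = 0.604 with an estimated correlation, 0.0636 without the smaller E14.5 sample, and upwards with 0.515 without E18.5). Of 30 synapse genes, the kinase gene Camk2b (0.39), the glutamate receptor gene Grin1 (0.49) and Dlg2 (0.28) rose and Gria3 fell by 0.24 (10 and 2 adjusted over the list alone, camera adjusted p = 0.000893, adjusted p = 0.254 with an estimated correlation). The call of Camk2b held whichever sample was left out. That of Gria3 ended without any single sample (−0.27 without E18.5), and that of Dlg2 without any but the smaller E14.5 sample (0.18 without E12.5 and 0.44 without E18.5). That of Grin1 ended without E12.5 (0.40), the larger or smaller E14.5 sample (0.44 and 0.50) or E16.5 (0.47), and without E18.5 it rose by 0.91. Of 35 axon guidance genes 6 rose and 2 fell, with Sema3c (0.56), Unc5d (0.47) and Epha4 (0.28) up and Slit1 (−0.43) and Plxnd1 (−0.68) down (10 and 4 adjusted over the list alone, camera adjusted p = 0.0716). Without E18.5 the calls of Unc5d (0.53), Epha4 (0.24), Slit1 (−0.34) and Plxnd1 (−0.84) ended. That of Epha4 also ended without E12.5 (0.23), that of Slit1 without the larger E14.5 sample (−0.40) or E16.5 (−0.43), and that of Plxnd1 without E12.5 (−0.36), E15.5 (−0.65) or E16.5 (−0.75). Late progenitor and glial genes were called up (6 of 18 rose, Ptn, Ntrk2, Cspg5, Luzp2, Cd9 and Sparcl1; 6 and 1 adjusted over the list alone, camera adjusted p = 0.00415, adjusted p = 0.178 with an estimated correlation). So were temporal transcription factors (4 of 18; 8 and 1 adjusted over the list alone, camera adjusted p = 0.0106, adjusted p = 0.390 with an estimated correlation, 0.106 without E12.5). Immediate early genes were called up (1 of 13, Fosb; 3 adjusted over the list alone, camera adjusted p = 0.0263, adjusted p = 0.376 with an estimated correlation, 0.301 without E18.5, 0.0617 without E12.5 and 0.053 without E16.5), beside mitochondrial shares of 3.83% at E12.5 and 7.53% at E18.5. Radial glia genes were called down (1 of 13 fell, Vim; 3 adjusted over the list alone, camera adjusted p = 0.00862, adjusted p = 0.269 with an estimated correlation), as were Notch pathway genes (1 of 11, Hey1; 1 adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.223 with an estimated correlation, 0.0561 without the smaller E14.5 sample and 0.0548 without E18.5). Intermediate progenitor genes were called down (2 of 16 fell, Nhlh1 and Rcor2, and Pcdh8, an adhesion gene, rose; 6 and 2 adjusted over the list alone, camera adjusted p = 0.00622, adjusted p = 0.318 with an estimated correlation). Neuroepithelial genes were called down as well (Igf2bp2 fell and Ptn rose among 14; 5 and 1 adjusted over the list alone, camera adjusted p = 0.0389, adjusted p = 0.318 with an estimated correlation, 0.68 without E18.5). The lists of G2 and M phase (0 of 24 passed, camera adjusted p = 0.09), S phase (0 of 25, 0.882), Wnt pathway (1 of 12 rose, 2 fell, 0.202) and cholesterol synthesis (0 of 20, 0.605) did not pass. Nor did erythroid (0 of 3, 0.605; median −0.02, mean −0.04, test up), extracellular matrix (3 of 18 rose, 2 fell, 0.504), glycolysis (0 of 18, 0.579) and pan-neuronal genes (1 of 25 rose, 1 fell, 0.501).

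**Figure D3:**
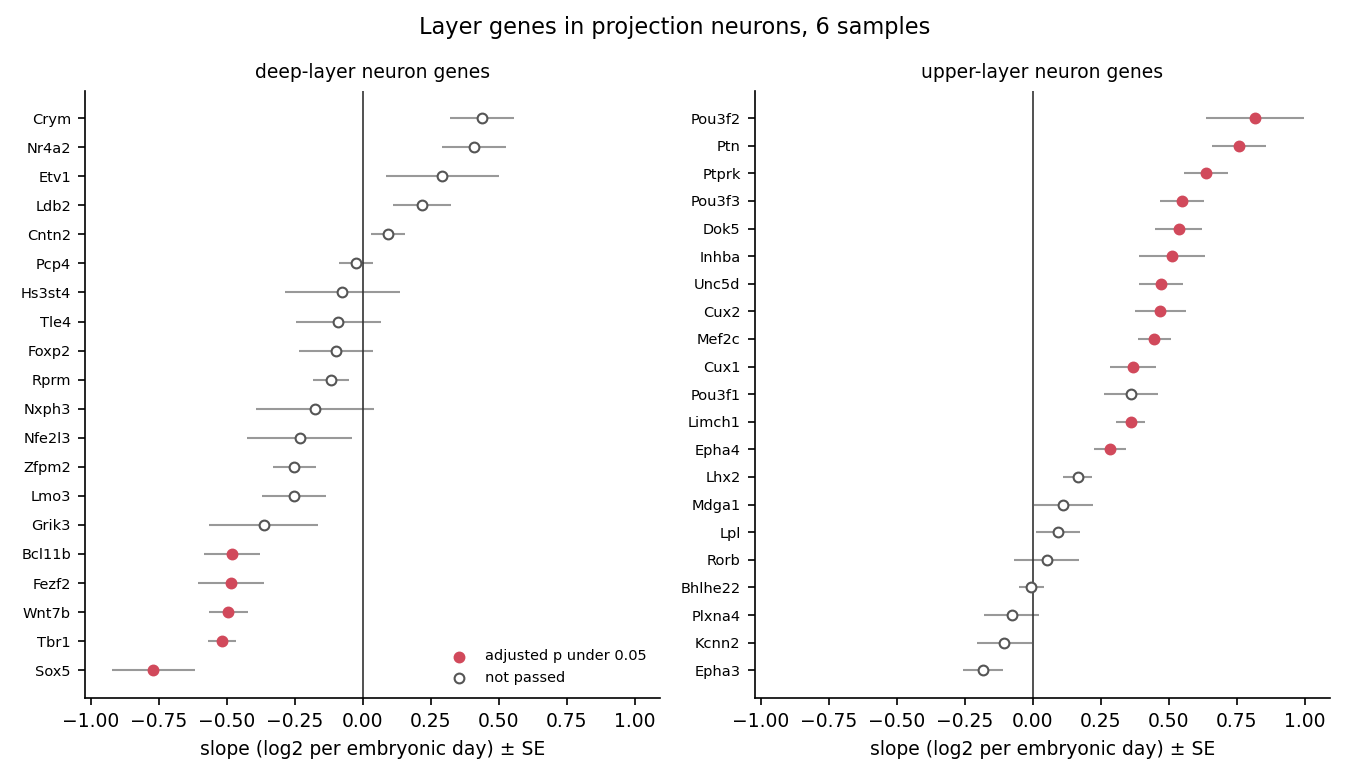
Slope on embryonic day in projection neurons in log2 units per day with its standard error (horizontal axis) for 20 deep-layer and 21 of the 22 measured upper-layer genes (vertical axis), with filled points for adjusted p under 0.05 in 6 samples. The 5 filled deep-layer genes lie below 0, Sox5 lowest at −0.77, and the filled upper-layer genes lie above 0, Pou3f2 highest at 0.82.

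The slopes of apical progenitors and projection neurons were compared directly in the 6 samples that held both, to ask which genes move over time differently in progenitors and their neuronal progeny. The slope of Sparcl1 (chromosome 5, 104079111 to 104113733, ENSMUSG00000029309) was lower in neurons by 1.23 log2 units per day (−1.23, SE 0.125, n = 6, edgeR adjusted p = 1.51e-05), with 1.55 in progenitors and 0.44 in neurons. The difference, neurons minus progenitors, was −1.22 for the glutamate transporter gene Slc1a2 (SE 0.0845, adjusted p = 3.96e-07), −0.92 for the lipid carrier gene Apoe, −0.91 for Egr1, −0.90 for Cdh13 and −0.87 for Camk2n1. It was 1.01 for Rgcc, 0.83 for the septin gene Sept6 (SE 0.119, adjusted p = 0.000411), 0.70 for Rcn1, 0.68 for Emx2, a cortical patterning gene, 0.68 for Tenm2 and 0.67 for Pou3f2 (SE 0.109, adjusted p = 0.00135, slopes of 0.21 in progenitors and 0.82 in neurons). Apoe, Rgcc and Rcn1 were not tested alone in neurons, nor Cdh13 in progenitors. In all, 212 genes had a higher slope in neurons and 234 a higher slope in progenitors among 10311 tested (interaction of class and day with sample as a block), 446 in total against 149 with DESeq2, 271 without the larger E14.5 sample and 171 without E18.5. Without E18.5 the differences of Sparcl1 (−0.76), Apoe (−0.92), Cdh13 (−0.67), Camk2n1 (−0.71), Rgcc (0.22) and Rcn1 (0.59) no longer passed. That of Rcn1 also ended with DESeq2 (0.71, adjusted p = 0.103), with at most 5% mitochondrial UMIs (0.46), with library suffix 2 (0.53), with thinned sums (0.50) and clustered anew at resolutions 1 (0.35) and 2 (adjusted p = 0.0743). That of Rgcc ended with at most 5% mitochondrial UMIs (0.83), with thinned sums (0.99) and at resolution 1 (0.60). With thinned sums Apoe had −1.07 (adjusted p = 0.434), and with at most 5% mitochondrial UMIs Cdh13 had −0.75 (adjusted p = 0.218).

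**Figure D4:**
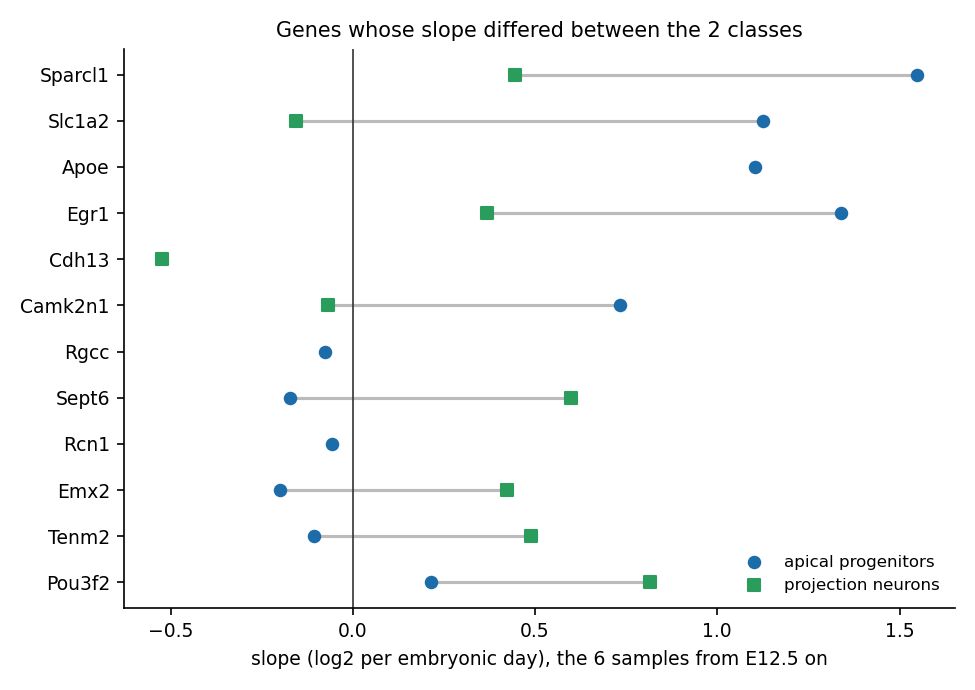
Slope in log2 units per day (horizontal axis) of 12 genes (vertical axis) in apical progenitors (circles) and projection neurons (squares), over the 6 samples from E12.5 on, with no marker where a gene was not tested in a class. Sparcl1 lies at 1.55 in progenitors and 0.44 in neurons, and Pou3f2 at 0.21 and 0.82.

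Calls were then set side by side across classes. Apical and intermediate progenitors shared 38 called genes among 5402 tested in both, all 38 in the same direction (26 up and 12 down, where independent lists would share 1.86 and 1.18). Apical progenitors and projection neurons shared 56 of 7604, with 51 in the same direction (41 up and 10 down, against 5.63 and 1.87), and intermediate progenitors and projection neurons 16 of 5318, with 14 in the same direction (9 up and 5 down, against 0.459 and 0.396). Zbtb20 rose in all 3 classes, at 0.61, 0.67 and 0.97. Classes of 1 sample share that sample's dissociation, library and free RNA, so part of the excess may come from the shared samples.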

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

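The tests that set the rise of pan-neuronal genes against RNA of projection neurons in 1 ratio, those of cluster 12 as the whole cause and as the source of single genes, those of immediate early genes and those of the order of days were chosen only after the results were seen. The difference of slopes between apical progenitors and projection neurons, a tested difference between groups, was called for 446 genes, and 5 of these were called in opposite directions in the 2 classes. These 5, named after seeing the values, were Lrpap1 (0.17 in progenitors and −0.29 in neurons), Pvrl3 (−0.16 and 0.39), Sept6 (−0.20 and 0.60), Tmem176b (0.38 and −1.15) and Vcan (0.18 and −0.32). No gene trend was fitted for some groups of cells as classes: 213 cells of cluster 14, 142 mesenchymal cells, 50 endothelial cells, 32 microglia, 25 mural cells and 13 erythroid cells.

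The rise of pan-neuronal genes in apical progenitors was weighed against RNA of neurons. For free RNA, the 9 genes that rose had a median level 5.82-fold that in endothelial, microglial and mural cells (interval 1.92 to 8.35), which left free RNA open. For doublets, the median slope in cells below the median UMI count was 1.08 times that in all cells (0.646 to 1.16), so doublets could be neither excluded nor shown. RNA of projection neurons added in 1 ratio for every gene was excluded, since the rise as a share of the neuronal level differed 6.07-fold between quartiles of genes (4.33 to 7.91), although other neurons as a source stayed open. Onset of neuronal transcription in late progenitors was not tested.

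The rise of late progenitor and glial genes was weighed against cells of cluster 12 joining the class. The median slope of 22 genes without cluster 12 was 0.813 times that with it (0.762 to 1.12), which left a part open, but 17 of the 22 were still called and the list kept adjusted p = 7.23e-17, so cluster 12 was excluded as the whole cause. For Olig1, Olig2, Egfr and Luzp2, the level without cluster 12 was 0.0609 of that with it (0 to 0.172). These 4 genes were the ones that could no longer be tested without it, so a low value was nearly fixed beforehand and their source stayed open. Free RNA from glial cells was excluded for the list as a whole. The 26 genes had in projection neurons a median of 0.0246 of their level in apical progenitors at E18.5 (0.00698 to 0.117). The highest single genes were Itm2b (0.830), Luzp2 (0.349), Ptn (0.330), Cspg5 (0.240) and Sparcl1 (0.209), for which it stayed open. Whether the rest is a change within progenitors or a change of cell types was not tested.

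The rise of immediate early genes was weighed against dissociation and RNA quality. Of 6 classes, 4 had a median slope above 0.1 log2 units per day. Interneurons (0.0972, single genes 0.0558 to 0.564) and Cajal-Retzius cells (0.0853, −0.0446 to 0.507) lay just under it. At least 2 classes under 0.1 had been set as the result against a response shared by all cells. In both classes the genes lay on either side of that limit, so the test decided neither for nor against such a response. The median mitochondrial share had r = 0.498 with embryonic day (exact permutation p = 0.259, two-sided; rho = 0.667, p = 0.117; r = 0.662 without the 2 farthest samples; n = 7), which could not tell either. In apical progenitors, the mean log2(CPM + 1) of the immediate early genes had r = 0.709 with the mitochondrial share and r = 0.866 with embryonic day. Both explanations stayed open, and a response of the tissue to its stage was not tested.

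Chance was tested by fitting 50 orders of the days. Only the real order gave as many genes for apical progenitors (781 genes, highest other order 40), projection neurons (299 against 122) and cells with Eomes (216 against 84). That is 1 of 50 orders, the smallest share the test can reach, so chance was made less likely there but not excluded. For intermediate progenitors, another order gave 88 genes against 78. The test does not tell stage apart from other differences between the samples.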

How the results depend on the processing

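The added tests in cluster 0, in interneurons, without cluster 12, without cluster 6, with cluster 0 added, without 1 library of E14.5, with erythroid cells kept, at clustering resolution 1, in intermediate progenitors alone, of differences clustered anew and of thinned ratios of named genes between neighbouring stages were chosen only after the data had been seen; the other alternatives were fixed before. Of 2686 alternatives for 139 called slopes of named genes, 2316 kept direction and call, 367 lost the call and 3 reversed. Of 629 for 30 uncalled slopes, 573 stayed, 16 gained a call and 40 reversed. Of 338 for 26 called lists, 272 stayed, 65 lost the call and 1 reversed, and of 240 for 12 differences 223 stayed and 17 lost the call. Of 208 for 16 identity genes with Eomes, none of them called, 21 reversed the direction. That none gained a call says little, since with 6 samples the smallest possible p was 0.03125, while in cells not thinned 5 genes reached an adjusted p of 0.05, at the threshold. No analysis paired across stages was possible because the stages share fewer than 2 replicate numbers. In the planned settings without an alternative, the smallest sum was 105152 UMIs in intermediate progenitors and 272600 in apical progenitors, both at E16.5. Where no cause is named below, the cause was not tested.

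The counts of called genes were 781 in apical progenitors, 78 in intermediate progenitors, 299 in projection neurons, 216 in cells with Eomes, 107 in cluster 0, 63 in interneurons and 446 for the difference. With no low count filter they were 1384, 268, 684, 553, 319 (cluster 0) and 756 (difference). With sums thinned, which leaves fewer counts, they were 415 (apical progenitors), 46 (intermediate progenitors), 117 (Eomes), 44 (cluster 0) and 202 (difference), the genes differing between E10.5 and E12.5 were 662 and those between the E14.5 samples 601, and slopes reversed for Neurog2 in apical progenitors (−0.023) and Sox2 in projection neurons (0.044). With library suffix 1, which has fewer samples, the counts were 238, 29, 49 (neurons), 77 (Eomes) and 177 (difference), no class share was called (apical progenitors r = −0.938, projection neurons r = 0.980, adjusted p = 0.0583 for both), and Sox2 in projection neurons had 0.089. With suffix 2, intermediate progenitors had 13 called genes and Eomes cells 107, Sox2 in apical progenitors had 0.0051 and Neurog2 in intermediate progenitors −0.0092.

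With at most 5% mitochondrial UMIs, which keeps fewer cells and left 4 samples in intermediate progenitors, cells with Eomes and cluster 0, 5 for the difference and 6 in the others, the counts were 273, 11, 110, 103, 42 (cluster 0) and 152 (difference). Slopes then reversed for Sox2 in apical progenitors (0.0089), Sox2 (−0.23), Neurog2 (−0.034) and Fezf2 (0.16) in intermediate progenitors, and Cdkn1a (1.20, adjusted p = 0.117), Pax6 (−0.027), Sox2 (−0.23), Neurog2 (−0.14) and Fezf2 (0.21) in cells with Eomes. With DESeq2, intermediate progenitors had 141 called genes and the difference 149. With the E14.5 samples summed, cluster 0 had 162. Without cluster 12, apical progenitors had 408, and Pax6 (0.042), Sox2 (0.038) and Bcl11b (0.045) reversed. Without cluster 6, Neurog2 had −0.063. With cluster 0 added, projection neurons had 652. Clustered anew at resolution 2, projection neurons had 465, and Neurog2 in apical progenitors (−0.016), Igfbp5 in intermediate progenitors (−0.22) and Sox2 in projection neurons (0.051) reversed. At resolution 1, Eomes (−0.099) and Neurog2 (−0.18) in apical progenitors and Igfbp5 (−0.26), Eomes (−0.015) and Neurog2 (−0.013) in intermediate progenitors reversed. On stage rank, Sox2 (0.0014) and Neurog2 (−0.0071) reversed in apical progenitors. Without doublets, Pax6 (0.045) and Sox2 (0.0086) reversed in projection neurons, and without 1 library of E14.5 Sox2 did there (0.0028).

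With each sample left out in turn, the counts ranged from 401 (without E10.5) to 886 (without the smaller E14.5 sample) in apical progenitors, 31 (E10.5) to 161 (E18.5) in intermediate progenitors, 147 (E16.5) to 311 (E12.5) in projection neurons, 102 (E12.5) to 239 (smaller E14.5) in cells with Eomes, 42 (E12.5) to 155 (smaller E14.5) in cluster 0, 20 (E16.5) to 134 (E18.5) in interneurons and 171 (E18.5) to 580 (E12.5) for the difference. In apical progenitors, Ccnd1 ranged from −0.42 (E18.5) to 0.020 (E10.5), Hes5 from −0.26 to 0.15, Eomes from −0.023 to 0.47, Pax6 from −0.26 to 0.094, Sox2 from −0.022 to 0.0050 and Neurog2 from −0.21 to 0.26. Neurog2 ranged from −0.053 to 0.13 in intermediate progenitors and −0.14 to 0.23 in cells with Eomes, Pax6 in cells with Eomes from −0.018 to 0.17 and Sox2 in projection neurons from −0.060 to 0.0097. Called class shares ranged from 1 (without E12.5) to 2. The correlation with day ranged from −0.961 to −0.807 for apical progenitors, −0.997 to 0.167 for intermediate progenitors, −0.596 to 0.694 for cluster 0, −0.679 to 0.7995 for Cajal-Retzius cells and −0.818 to 0.529 for cluster 14.

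For identity genes with Eomes, intermediate progenitors and neurons alone gave Tbr1 −0.91, Fezf2 −0.35, Cux2 −0.13 and Neurod6 −1.83. Intermediate progenitors alone gave Tbr1 −0.17, Bcl11b 0.045, Fezf2 −0.053, Sox5 0.58, Cux1 −0.32, Cux2 −0.81 and Bhlhe22 1.10, and Foxp2 0.36, Pou3f2 0.12, Pou3f3 0.04, Mef2c −0.44 and Tle4 −0.64, these 5 all nearer 0 than in the 3 classes pooled. Cells not thinned gave Cux2 −0.0062 and Neurod2 0.75. Leaving out samples gave ranges of −0.57 to 0.82 for Tbr1, −0.097 to 0.32 for Fezf2, −0.60 to 0.093 for Sox5, −0.85 to 0.099 for Neurod2, −0.074 to 1.07 for Neurod6 and −1.17 to 0.0095 for Bhlhe22. An estimated correlation left 2 called lists and fry 17, and the deep-layer list in projection neurons ranged from adjusted p = 1.365e-08 (without E12.5) to 0.515, upwards, without E18.5. At 100 CPM or more, 131 genes differed between E10.5 and E12.5 and 72 between the E14.5 samples, and at 3-fold 100 and 26.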

Other observations

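The tests below, on interneurons, cluster 0, cluster 14 and mesenchymal cells, were chosen only after the data had been seen. Interneurons, the GABAergic cells that enter the cortex from the ventral forebrain (cluster 8, led by Sst, Lhx6, Gad1 and Gad2), numbered 436 and were followed over 7 samples. There were 30 at E10.5, 50 at E12.5, 89 and 33 at E14.5, 72 at E15.5, 46 at E16.5 and 116 at E18.5. Changes within interneurons were not told apart from a change of the cell types in the cluster. The transcription factor gene Six3 fell by 1.26 log2 units per day (SE 0.225, edgeR adjusted p = 0.0052, 254 to 0 CPM, where 3 counts at E18.5 would give 14.49 CPM), Zfhx4 by 1.13, Isl1, a striatal regulator, by 0.76, Zfhx3 by 0.73, Tle4 by 0.63, Pou3f4 by 0.63 and Pax6 by 0.61, and the filament gene Nes by 0.57. Higher at later stages were Limch1 (0.87, SE 0.124, adjusted p = 0.00166, 0 to 505 CPM, where 3 counts at E10.5 would give 28.2 CPM), the glutamate receptor gene Gria3 (0.81), the nuclear factor genes Nfib (0.67, 0 to 1564 CPM) and Nfix (0.65), the RNA-editing gene Adarb2 (0.65), Tcf4 (0.56, 161.5 to 5525 CPM), Akap7 (0.56) and Fos (0.56). Gria3 fell in projection neurons by 0.24. In all, 42 genes rose and 21 fell among 3379 tested, 63 in total against 23 without E10.5 or E12.5, 41 without E15.5, 20 without E16.5 and 134 without E18.5. Without E16.5 the calls of Isl1 (−0.71), Zfhx3 (−0.72), Pou3f4 (−0.58), Pax6 (−0.61) and Fos (0.61) ended, and without E18.5 those of Nfix (0.68) and Fos (0.69). The call of Fos held only when the larger E14.5 sample was the one left out.

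Cluster 0, 1812 cells with genes of intermediate progenitors and of neurons, was followed over 6 samples from E12.5 on. Its steepest falls were of Ppap2b (−0.76), the Notch ligand gene Dner (−0.66, SE 0.0834, adjusted p = 0.000533, 240 to 22.5 CPM), St18 (−0.53), Cabp1 (−0.53), Bcl11b (−0.52, 611 to 82.4 CPM), Cdc42ep3 (−0.51), Gadd45g (−0.48) and Acvr2b (−0.47). Its steepest rises were of Egr1 (0.86), Sh3rf3 (0.78), Zbtb20 (0.68, SE 0.0670, adjusted p = 5.3e-05, 149 to 2074 CPM), Pou3f2 (0.65, 69.1 to 880 CPM), Osbpl6 (0.63), Echdc2 (0.54), Fam3c (0.54) and Nav2 (0.54). In all, 63 genes rose and 44 fell among 7347 tested, 107 in total against 42 without E12.5 and 67 without E18.5. Without E12.5, 9 of 16 calls of these genes ended, among them Dner (−0.43), Ppap2b (−0.48) and Pou3f2 (0.51), and without E18.5 those of Bcl11b (−0.41) and Egr1 (0.26). Of 7305 genes tested in both, cluster 0 and projection neurons shared 49 calls, 31 up and 18 down, where independent lists would share 0.949 and 0.524. Both come from the same samples, so the shared calls are not independent evidence.

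Cluster 14 held 213 cells, 175 of them from E10.5. Genes of the cortical hem, the signalling centre beside the early cortex, define it and were seen in it far more often than elsewhere: Wnt8b in 71.4% of its cells (median 3192 UMIs) against 0.737% of 10035 other cells (median 1952 UMIs), Rspo1 in 55.9% against 0.628%, Rspo2 in 55.9% against 0.568%, Lmx1a in 16.9% against 0.239% and Wnt3a in 15.96% against 0%. Mesenchymal cells, 142 in all, came only from E10.5, with Col3a1 in 90.1% (median 3838 UMIs) against 0.277% of 10106 other cells (median 1961 UMIs), Col1a2 in 84.5% against 0.485%, Lum in 57.0% against 0.0297% and Twist1 in 49.3% against 0.119%.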
